A study of Homo sapiens with 6 samples.

How the data were processed

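RNA of 6 cultures of SKOV3, an established human ovarian carcinoma cell line, was measured by RNA sequencing. In 3 cultures the gene JUP was knocked down (shJUP 1 to 3), and 3 carried the control construct (shNC 1 to 3). Per the labels' protocols, the replicates were independent biological replicates, messenger RNA was enriched with oligo(dT) beads, and the libraries were sequenced on a DNBSEQ instrument. The deposited table holds estimated counts of reads per Ensembl gene, not scaled between libraries. Per the submitters' processing notes, RSEM 1.3.3, STAR 2.7.9a, DESeq2 1.26.0 and edgeR 3.32.1 were used, with no role given for each. The labels' protocols also describe FPKM values from Cuffdiff, which are not used here. The genome build, the annotation release and the strand setting are not given in the sources used here, so no coordinates are printed, and antisense or overlapping genes cannot be separated from their partners.

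The table had 60695 rows. Of these, 31 held fragments of gene ontology text in place of a gene ID and were left out, which left 60664 genes, and 60463 of their IDs were matched to a gene symbol. The expected counts were not whole for 33.9% to 36.3% of the genes above 0, depending on the library, and were rounded to whole numbers before any fit. Library totals were 17456121, 18908278 and 18630181 for shJUP 1 to 3 and 18157973, 19279514 and 18570520 for shNC 1 to 3. The 10 most abundant genes took 5.2% to 7.8% of the counts. Replicates of a group differed by far more than sampling noise (chi-square per gene 10 to 61.3), so none was treated as a repeat deposit of another. Intervals on counts cover counting error only.

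The main comparison used edgeR 4.0.16 in R 4.3.3: the filterByExpr filter, which kept 15867 genes, TMM scaling (factors 0.978 to 1.028), and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are given as CPM after TMM scaling, as mean ± SD with n = 3 per group. Log2 fold changes are shJUP over shNC. Their standard error (SE) was back-calculated from the edgeR test, as the absolute log2 fold change over the square root of the F statistic. The biological coefficient of variation was 24.2%. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 31 lists of at least 5 tested members, with JUP left out of every list. A further 5 lists of markers of other cell types were read as levels only.

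The design, the gene lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule took 13 genes whatever their values, the 10 higher and 10 lower genes with the largest fold change past the threshold with a mean of at least 5 CPM and no overlap between groups, the 3 higher and 3 lower with a mean of at least 100 CPM, and up to 4 members of each list with the smallest p-values. The edgeR test called no gene, so the parts of the rule that need called genes had nothing to act on. They were applied to the genes called by DESeq2 1.42.0 (a test chosen beforehand as a second tool), a choice made after the data were seen. Of the genes the rule takes, 2 are not reported here.

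The gene count was computed under 19 settings in all. Those chosen beforehand were other scalings, no filter or a stricter filter (1 CPM in 3 libraries), DESeq2, limma-voom, a block for the library number, and each library left out in turn. Settings added after the data were seen were leaving out both number-2 libraries (with edgeR and with DESeq2), the edgeR likelihood-ratio test, and DESeq2 and limma-voom with the block. The numbers in the labels were checked as pairs. Deviations from the group means correlated at 0.14, 0.51 and 0.20 between libraries of number 1, 2 and 3, each over the limit set for treating numbers as pairs, so the blocked value is printed beside a result where it changes a call. The pairing is uneven: shJUP 3 correlated at 0.39 with shNC 1, more than with its own number, and shJUP 1 at 0.15 with shNC 3. The labels do not say what a number stands for.

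The steps were tested on simulated counts for the 15867 genes with 200 changed genes, all with a mean of at least 5 CPM. Counts were drawn independently for each library, with nothing shared between libraries of the same number. The shares recovered therefore need not hold in the real libraries. At the spread estimated per gene, edgeR recovered 48% of the 2-fold and 100% of the 4-fold changes and called 12 unchanged genes. DESeq2 recovered 79% and 100% and called 52 unchanged genes. With a spread common to all genes, edgeR recovered 43% and DESeq2 47% of the 2-fold changes. They called 5 and 16 unchanged genes there. Gene length and GC content for the bias checks came from GENCODE release 29, which held 98.7% of the tested genes.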

Results

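Gene expression was measured in SKOV3, a human ovarian carcinoma cell line, after knockdown of JUP with a short hairpin RNA (shJUP, 3 libraries) and in cells with a control hairpin (shNC, 3 libraries). JUP encodes plakoglobin (gamma-catenin), a protein of desmosomes and adherens junctions. The title of the series places JUP upstream of PDGFB, a ligand of the PDGF receptors, and of JAK-STAT signalling. The comparison asks what differs in the transcriptome, and in those genes, between cells with the shJUP and the control hairpin. Other effects of the hairpin cannot be told apart from those of lower JUP in this design. Library totals ranged from 17456121 to 19279514 estimated counts.

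The targeted gene was lower in each shJUP library than in each control, but unevenly. JUP (ENSG00000173801) stood at 39.9, 93.6 and 24.6 CPM in shJUP 1, 2 and 3 and at 104, 133 and 101 CPM in shNC 1, 2 and 3, or 52.7 ± 36 against 113 ± 17 CPM (SD, n = 3 each). The library shJUP 2 kept 83% of the mean control level, whereas shJUP 1 and 3 kept 35.4% and 21.9%. Against the control of the same number the ratio was 0.384 (95% counting interval 0.352 to 0.419) for number 1, 0.705 (0.663 to 0.75) for number 2 and 0.243 (0.219 to 0.269) for number 3. The log2 fold change was -1.10 (SE 0.44), which did not pass the edgeR quasi-likelihood test (adjusted p = 0.47, unadjusted 0.040 from the same edgeR fit). With a block for the library number it was -1.30 (edgeR adjusted p = 0.12), and DESeq2 with that block gave an adjusted p of 0.048. Without both number-2 libraries it was -1.66, with an adjusted p of 0.051 by edgeR and 4.9e-11 by DESeq2, a choice made after the data were seen. JUP passed in these 2 DESeq2 fits and in no other setting run.

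PDGFB (ENSG00000100311) was expressed at very low levels, with 11, 29 and 7 counts in shJUP 1 to 3 and 29, 63 and 52 counts in shNC 1 to 3. Its level was 0.844 ± 0.62 CPM in shJUP and 2.59 ± 0.9 CPM in shNC (SD, n = 3 each), and each shJUP library lay below each control. The log2 fold change of -1.61 (SE 0.55) did not pass the edgeR test (adjusted p = 0.44). At this depth PDGFRB, the main receptor of the ligand, had 1 to 6 counts per library and was not tested, and PDGFRA was at 1.36 ± 0.62 against 1.7 ± 1.3 CPM (log2 -0.32, SE 0.59). Of the 6 tested PDGF ligands and receptors none passed, and the list did not either (camera adjusted p = 0.22).

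**Figure D1:**
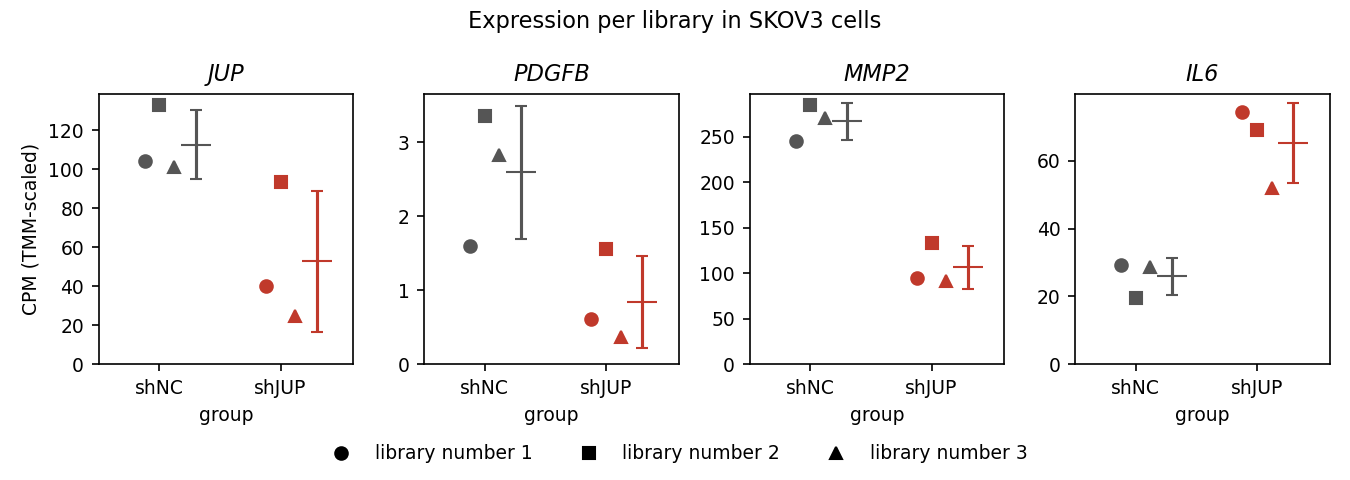
CPM after TMM scaling (vertical axes) of JUP, PDGFB, the protease gene MMP2 and the cytokine gene IL6 in the 3 shNC and 3 shJUP libraries. Symbols mark the library number, bars the mean and SD, and JUP in shJUP 2 (93.6 CPM) lies close to the lowest control (101 CPM).

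The JAK-STAT genes named here did not pass the edgeR test. These are transcript levels, and activity of the pathway was not measured. JAK1 (log2 0.03, SE 0.12), JAK2 (0.14, SE 0.16), STAT3 (-0.13, SE 0.17) and STAT5A (-0.07, SE 0.25) differed by less than or about their standard error. STAT5B was at 103 ± 10 against 135 ± 17 CPM (log2 -0.40, SE 0.13, adjusted p = 0.43 by edgeR) and SOCS3, a feedback inhibitor, at 22.3 ± 4.8 against 16.2 ± 8.4 CPM. The 28 genes of the JAK-STAT core and its feedback did not shift as a list (camera adjusted p = 0.56). STAT2 had the smallest p-value among them, at 33.3 ± 5.2 against 47.1 ± 2.4 CPM (log2 -0.50, SE 0.14, adjusted p = 0.40 by edgeR). DESeq2 called STAT2 lower with the block (adjusted p = 0.036) and not without it (0.15). Among 32 cytokines and receptors that signal through the pathway, 4 were higher and 1 lower by edgeR when adjusted over the list alone. DESeq2 over all genes called 4 higher and 1 lower, and 4 higher and 2 lower with a block for the library number. The edgeR test over all genes called none, and the list did not pass (camera adjusted p = 0.22). IL6 was at 65.2 ± 12 against 25.9 ± 5.5 CPM (log2 1.33, SE 0.20, adjusted p = 0.32 by edgeR and 7.4e-06 by DESeq2). IL11 was at 12.6 ± 3.9 against 3.02 ± 1.5 CPM (log2 2.05, SE 0.44, adjusted p = 0.34 by edgeR and 5.4e-04 by DESeq2), and LIFR, a receptor of this cytokine family, at 62.8 ± 8.4 against 36.2 ± 4.5 CPM (log2 0.79, SE 0.15). The 28 STAT3 target genes did not pass as a list (camera adjusted p = 0.13), but did with the block (adjusted p = 0.011, lower), and not with the block and an estimated correlation (adjusted p = 0.85).

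Across the transcriptome the edgeR quasi-likelihood test called 0 of 15867 genes, with a smallest adjusted p of 0.28. At an unadjusted p under 0.05 the same edgeR test held 1594 genes, where independent tests would give 793 by chance. Other splits of the 6 libraries gave 1334 to 2081 where both number-2 libraries stayed together. Those that part them, as the real split does, gave 82 to 265. No overlap between the groups was seen for 2704 genes (17%, against 10% by chance). DESeq2 called 179 genes, 100 higher and 79 lower in shJUP, of which 75 differed at least 2-fold. With the library number as a block edgeR called 1 gene, MMP7, which was lower (log2 -2.71, adjusted p = 0.034), and DESeq2 called 696. Leaving out both number-2 libraries, a choice made after the data were seen, gave 49 genes with edgeR. Of the 179 DESeq2 calls, 166 were among the 696 and 29 among the 49, each in the same direction. The genes that the naming rule took from the calls are DESeq2 calls which edgeR did not make with its filter. Without the filter edgeR called 5 genes, among them NREP, MMP2, TLL1 and PLEKHB2.

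Among the genes lower in shJUP, several encode matrix proteins and enzymes that act on matrix. Of the 55 tested members of the matrix and protease list, 33 lay below 0 and 22 above, among the latter TNC (log2 1.09, SE 0.60). COL5A1, a fibrillar collagen chain, was at 189 ± 100 against 638 ± 39 CPM (log2 -1.75, SE 0.41, DESeq2 adjusted p = 7.6e-04). MMP2, a gelatinase, was at 106 ± 23 against 267 ± 20 CPM (log2 -1.33, SE 0.17, DESeq2 adjusted p = 1.3e-08). TLL1, a tolloid-like metalloprotease, was at 5.77 ± 1.5 against 23.2 ± 6.8 CPM (log2 -2, SE 0.29). FBN1 (log2 -0.78, SE 0.16), COL12A1 (-0.88, SE 0.21) and TGFBI (-0.97, SE 0.16) were lower as well. NREP had the smallest DESeq2 adjusted p (1.6e-11), at 68.2 ± 20 against 254 ± 32 CPM (log2 -1.90, SE 0.22). The other lower genes by the naming rule were PI16 (log2 -4.52, SE 1.15), RASSF9 (-2.43), DIO2 (-2.15), NEDD9 (-1.72), EML5 (-1.63), the antisense RNA STARD4-AS1 (-1.61, uncertain because strand use is not known) and SPOCK1 (-1.53). SPOCK1 passed with DESeq2 (adjusted p = 0.0031) and not with the block in DESeq2 (adjusted p = 0.070). PI16 was at 14.1 ± 18 CPM in the controls, a spread larger than its mean.

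Among the genes higher in shJUP, AXL, a receptor tyrosine kinase, was at 442 ± 130 against 172 ± 49 CPM (log2 1.36, SE 0.28, DESeq2 adjusted p = 5.4e-04). PLEKHB2 was at 138 ± 6.8 against 62.1 ± 8.4 CPM (log2 1.16, SE 0.13, DESeq2 adjusted p = 1.5e-09), and ABL2, a non-receptor tyrosine kinase, at 167 ± 47 against 76.7 ± 13 CPM (log2 1.12, SE 0.24). FGF5, a fibroblast growth factor, had a log2 fold change of 1.52 (SE 0.46), MZT1, a subunit of the gamma-tubulin ring complex, 1.43 (SE 0.25), MEGF6 1.37 (SE 0.26) and PIK3AP1 1.95 (SE 0.42). MOK (log2 2.24, SE 0.63) was at 24.1 ± 23 CPM in shJUP, a spread close to its mean, and its DESeq2 adjusted p of 0.0051 became 0.16 with the block. SPANXA1 (log2 1.55) and SPANXA2 (log2 1.70) are near-identical copies that share reads and are uncertain.

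**Figure D2:**
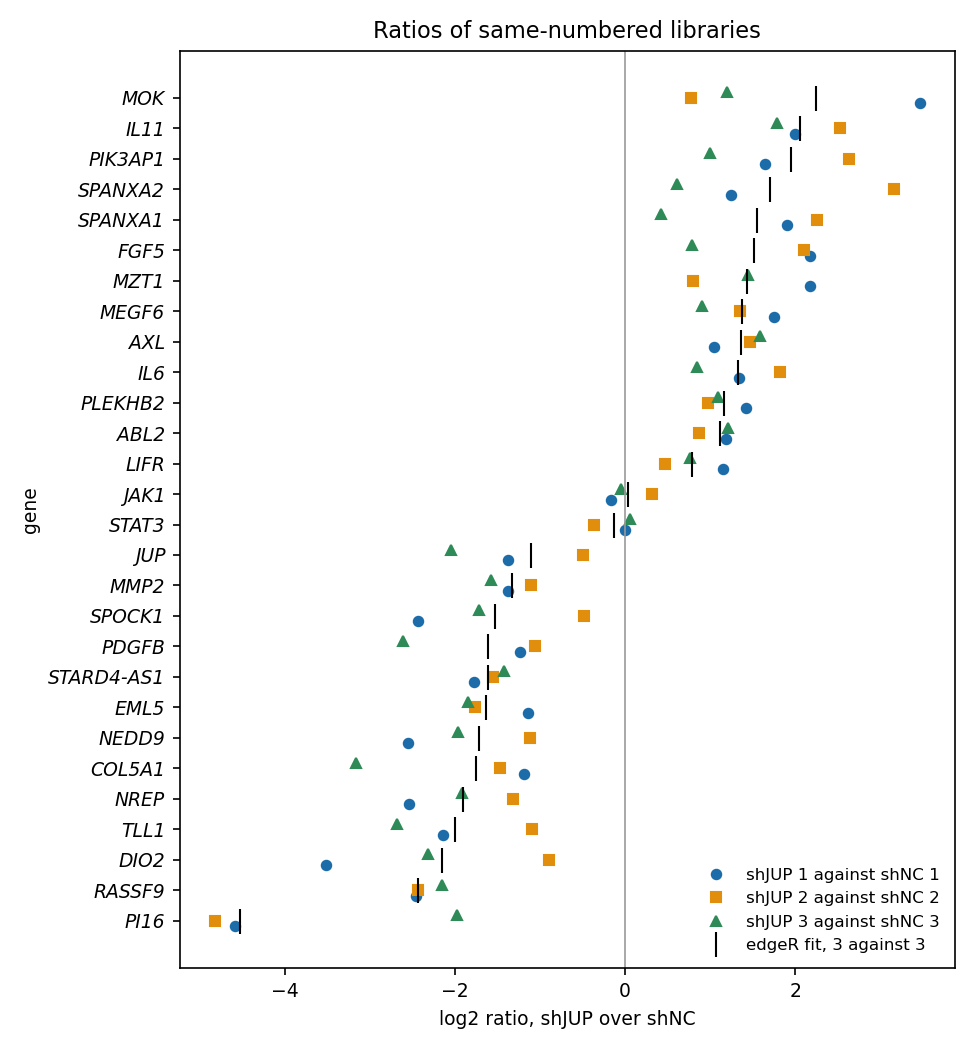
Log2 ratio of shJUP over shNC (horizontal axis, log2 CPM with a prior count of 2) for JUP, PDGFB, IL6, LIFR, JAK1, STAT3 and the genes named by rule from the DESeq2 calls. Coloured symbols are the ratios of same-numbered libraries and black bars the edgeR fit. The JUP ratio of number 2 lies nearest to 0. All plotted genes except JAK1 and STAT3 lie on 1 side of 0 in all 3 numbers. For genes taken under the rule's condition of no overlap between groups, that condition fixed this beforehand.

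Of 31 gene lists, 7 passed the camera test with the preset correlation and 0 with a correlation estimated for each list (adjusted p = 0.82 for each of the 7), so the directions below rest on the preset value. Every one of the 9 other ways of splitting the 6 libraries also gave at least 7 lists. The 40 genes of mitosis and G2/M were higher (camera adjusted p = 4.2e-05, median log2 0.19), with 36 above 0 and examples PRC1 (0.47, SE 0.11) and TOP2A (0.35, SE 0.12). This list lost its call without shNC 2 (adjusted p = 0.19 by camera). The 27 NF-kB target genes were higher (adjusted p = 6.3e-04, median 0.39), among them IL6 and TRAF1 (1.82, SE 0.48), and lost the call without shJUP 2 (0.74). The 55 genes of extracellular matrix and proteases were lower (adjusted p = 0.0023, median -0.31), with 33 below 0. DESeq2 called 4 of them lower, and with the block 14 lower and 1 higher. This list missed the threshold without shJUP 3 (0.058). The 13 mitochondrially encoded genes were lower (0.0023, median -0.30) and the 17 heat shock proteins higher (0.0023, median 0.23), and both lost the call without shJUP 1 (0.18 and 0.15), as the heat shock list also did without shNC 2 (0.098). The 42 genes of DNA replication and G1/S (adjusted p = 0.010) lost the call without shJUP 3 (0.42) and turned direction without shNC 2 (0.90). The 28 immediate early genes were higher by camera (0.046), but with a median log2 of 0.06, 15 above 0 and 13 below. They include KLF6 (log2 0.96, SE 0.24) and KLF2 (1.19, SE 0.28). This list lost its call without shJUP 2 (0.27), shJUP 3 (0.13) or shNC 3 (0.10), and turned direction without shNC 1 (0.95). With the library number as a block 10 lists passed, since the immediate early list dropped out (adjusted p = 0.066) and others entered. These were the STAT3 target (0.011, lower), YAP/TAZ target (0.010, higher), interferon response (0.010, lower) and angiogenic factor (0.044, higher) lists. Their median log2 without the block was -0.14, 0.03, 0.01 and -0.05 in that order. With the block and an estimated correlation 0 lists passed (adjusted p = 0.85 for these 4 lists).

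The junction genes around JUP did not move as lists. The 8 tested desmosome genes (camera adjusted p = 0.62) included DSP at 409 ± 2.2 against 456 ± 25 CPM (log2 -0.16, SE 0.09) and DSC2 at 31.7 ± 5.6 against 41.4 ± 4.8 CPM (log2 -0.39, SE 0.16). Of 18 adherens junction genes (0.90), DESeq2 called CTNNAL1 higher (log2 0.79, SE 0.17) and CDH6, a cadherin, lower (187 ± 67 against 466 ± 120 CPM, log2 -1.31, SE 0.29). With the block DESeq2 also called CTNND1 lower (log2 -0.47, adjusted p = 0.013, against 0.14 without the block). CTNNB1, which encodes beta-catenin, was at 311 ± 30 against 273 ± 22 CPM (log2 0.19, SE 0.12), and CDH1 had 0 to 40 counts per library and was not tested. Tight junction (0.39), epithelial (0.91), mesenchymal (0.13), integrin (0.10), Wnt/beta-catenin target (0.39), YAP/TAZ target (0.13), receptor tyrosine kinase (0.17), angiogenic factor (0.23), interferon response (0.18), hypoxia (0.17), glycolysis (0.28), nuclear oxidative phosphorylation (0.096), ribosomal protein (0.11), cholesterol synthesis (0.93), stress response (0.62), apoptosis (0.68), histone (0.83) and ovarian carcinoma marker (0.93) lists did not pass the camera test at these adjusted p-values. The interferon response list passed as lower without shJUP 2 (adjusted p = 4.8e-14) and without both number-2 libraries (1e-14), and turned direction without shJUP 1 (0.59) or shJUP 3 (0.62). These values rest on the preset correlation, and over all 6 libraries the list had an adjusted p of 0.90 with an estimated correlation and 0.85 with the block as well. No member of any list passed the edgeR test over all genes. Adjusted over the list alone, edgeR called 3 higher and 1 lower among apoptosis regulators, 1 higher and 2 lower among STAT3 targets, 2 lower among matrix and protease genes, 2 higher among receptor tyrosine kinases, 1 higher and 1 lower each among adherens junction and mesenchymal genes, 1 higher each among NF-kB, YAP/TAZ and Wnt/beta-catenin targets and angiogenic factors, and 0 in the lists not yet counted. Markers of other cell types were read as levels. Of 11 leukocyte markers 1 reached 1 CPM in any library (CD68, up to 35.8 CPM), and of 10 markers of neural and embryonic kidney lines 0 did. Of 10 fibroblast markers 7, of 10 endothelial markers 6 and of 8 mesothelial markers 4 reached 1 CPM, with PDPN at up to 22.4 CPM and LRRN4 at up to 36.7 CPM. COL1A1 varied without regard to group, at 253, 32.3 and 8.76 CPM in shJUP 1 to 3 and 38.3, 401 and 49.3 CPM in shNC 1 to 3.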

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

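The settings without both number-2 libraries, the edgeR likelihood-ratio test, and DESeq2 and limma-voom with the block were chosen after the data were seen. The count of called genes depends on the test: 0 with edgeR at any scaling tried, with the stricter filter, with limma-voom and with each library left out, 5 without the filter (NREP, BGN, MMP2 and TLL1 lower and PLEKHB2 higher, looked up after their values were seen), 1 with the replicate block in edgeR and 1 in limma-voom with the block (MMP7 in both), 49 without both number-2 libraries, 127 with the likelihood-ratio test, 179 with DESeq2, 696 with DESeq2 and the block, and 643 with DESeq2 without both number-2 libraries. At least 2-fold the counts were 5 without the filter, 1 with the replicate block in either tool, 43, 63, 75 and 137 in the same order up to the blocked DESeq2 fit. The cause was not tested. JUP stayed lower in all settings. It was -1.30 with DESeq2 and the block, past the threshold (adjusted p = 0.048), and -1.66 with DESeq2 without both number-2 libraries (adjusted p = 4.9e-11), against adjusted p-values of 0.051 to 0.89 elsewhere, and ranged from -1.80 without shJUP 2 to -0.75 without shJUP 3. PDGFB stayed lower, from -2.38 to -1.26 with 1 library left out, and passed in no setting that gave it an adjusted p. DESeq2 with the block gave PDGFB none, and DESeq2 without both number-2 libraries gave 0.091. The number of lists past camera was 7, and 12 without the filter, 12 without both number-2 libraries, 10 with the replicate block, 0 with an estimated correlation, 0 with fry for a shift in 1 direction, 3 with fry for changes in either direction, and 5 to 12 with 1 library left out (12 without shJUP 2, 11 without shNC 1).

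Genes that missed the threshold and changed direction were, as log2 fold changes with 1 library left out, PDGFRA (-0.76 to 0.55), JAK1 (-0.06 to 0.09), STAT3 (-0.23 to 0.09), STAT5A (-0.18 to 0.03) and PDGFRL (-1.26 to 0.72). Without both number-2 libraries PDGFRA was at 0.12, JAK1 at -0.09, STAT3 at 0.04 and PDGFRL at 0.38. Lists that changed direction with 1 library left out had these lowest and highest camera adjusted p-values over the 6 fits: adherens junction 0.51 and 0.86, tight junction 0.097 and 0.89, epithelial program 0.2 and 0.99, STAT3 target genes 0.0041 and 0.85, interferon response 4.8e-14 and 0.62, Wnt/beta-catenin target genes 0.41 and 0.99, DNA replication and G1/S 1.2e-05 and 0.9, apoptosis regulators 0.52 and 0.99, hypoxia response 0.0015 and 0.66, glycolysis 0.019 and 0.89, cholesterol synthesis 0.45 and 0.88, stress response 0.015 and 0.9, immediate early genes 6.7e-06 and 0.95, ovarian carcinoma markers 0.43 and 0.95, ribosomal proteins 0.00053 and 0.83, replication-dependent histones 0.18 and 0.95. Other settings that turned a list gave adjusted p-values of 0.32 with the replicate block and 0.055 without both number-2 libraries for the epithelial program, 0.93 for tight junction, 0.46 for apoptosis and 0.60 for cholesterol synthesis without both number-2 libraries, 0.94 for cholesterol synthesis with limma-voom, and 0.86 for ovarian carcinoma markers and 0.82 for histones without the filter. The cause was not tested. Low counts limit PDGFB, PDGFRA, PDGFRB and CDH1.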

Other observations

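The tests of JUP in shJUP 2 and of fibroblasts in the number-2 cultures were chosen or changed after the results they measure had been seen, and the genes of this paragraph were looked up after their values were known. Of 11 ligands of the EGF receptor family looked up, 8 could be tested, 6 of these were higher in shJUP without overlap, and edgeR called 0, DESeq2 3 and DESeq2 with the block 4. No test of the family as a list was run. TGFA was at 160 ± 6.2 against 102 ± 5.6 CPM (log2 0.65, SE 0.10, adjusted p = 0.32 by edgeR and 8.3e-05 by DESeq2), HBEGF at 23.1 ± 5.9 against 9.1 ± 0.9 CPM (log2 1.34, SE 0.22) and EREG at 57.4 ± 32 against 8.55 ± 7.3 CPM (log2 2.74, SE 0.68, DESeq2 adjusted p = 0.066, and 0.029 with the block). NRG4 was at log2 -0.03 (SE 0.49), and NRG1 overlapped between the groups, at 122 ± 73 against 66.5 ± 8.3 CPM. BGN, which encodes the matrix proteoglycan biglycan, had 0 counts in each shJUP library and 45, 88 and 30 counts in shNC 1 to 3, at least 54.5-fold lower when 3 counts over the group are taken as the floor (adjusted p = 0.32 by edgeR and 1.3e-06 by DESeq2).

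JUP in shJUP 2 lay closer to the controls than in shJUP 1 and 3. A state shared by the number-2 libraries that raised JUP alike in both stays open: the ratio of shJUP 2 to shNC 2 was 0.705 beside 0.384 and 0.243 for the other numbers, but its interval covers counting error only and the ratio restates the pattern. A wrong label and a weaker knockdown stay open too, and both rest on a score over 200 genes picked from the other 4 libraries, with 0 at the controls and 1 at the other shJUP libraries. The score of shJUP 2 was 0.35 over all such genes and 0.39 over genes steady between the controls, between the bounds of 0.25 for a control and 0.5 for a knockdown, while against its own control it was 0.48 (beside 0.61 and 0.53 for numbers 1 and 3) and 0.42 over the steady genes (beside 0.86 and 0.76). These tests were revised after their results were known: 0.48 met the first criterion for a weaker knockdown, below both others, and missed the stricter one adopted later, below both by more than they differ, and a further version with steady genes and bounds from the control scores would have decided both questions and was set aside because it was chosen from the answer.

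Other values bear on a wrong label without deciding it. In shJUP 2, 186 of the 200 steady genes differed from shNC 2 in the direction of the other shJUP libraries, beside 183 and 192 for numbers 1 and 3, and BGN had 0 counts there. Exchanging the labels of shJUP 2 and shNC 2 left 2 genes called by DESeq2.

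A set of 100 genes was at least 2-fold higher in both number-2 libraries than in each other library of their group, where 5.4 would be expected if the groups were independent. The same count was 2 for number 1 and 0 for number 3, where the expected count rounds to 0 for each. The first principal component (44.8% of the variance) set the number-2 libraries apart. Examples, picked after their values were seen, are C3 (556 and 587 CPM in shJUP 2 and shNC 2, against 29.2 to 91.9 CPM elsewhere) and CP (106 and 515 CPM). The set holds 5 of 21 NF-kB target genes (Fisher's exact test, one-sided, adjusted p = 2.5e-05 over 29 lists) and 3 of 14 epithelial genes (0.0032). That test treats genes as independent, while the set is defined by the number-2 libraries alone. Its p-values therefore do not measure the spread between cultures. Leukocytes are argued against by a summed level of 0.21 CPM of PTPRC, TYROBP and FCER1G, and a bias of gene length or GC content by a median log2 excess of 1.6 after its removal (1.82 before). Fibroblasts stay open: summed COL1A1, COL1A2 and COL3A1 were lower in shJUP 2 than the mean of the other libraries of its group (log2 -2), which rests on shJUP 1 (266 CPM, against 34 in shJUP 2 and 9.19 in shJUP 3), while LUM is among the 100 genes and DCN was at 5.87 and 7.54 CPM in shJUP 2 and shNC 2 against 0.553 to 2.45 CPM elsewhere. A difference in culture condition or day is a candidate explanation that the labels do not allow to be tested.

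The list of extracellular matrix and proteases lay lower in shJUP by the camera test with the preset correlation. A bias of gene length or GC content is argued against by a median log2 fold change of -0.24 after its removal (-0.31 before), and fibroblasts in the controls by COL1A1 and COL1A2, whose lowest control sum was 3.4% of the summed difference of MMP2, COL5A1, FBN1 and TGFBI. A response of the matrix genes to lower JUP is a hypothesis found and examined on the same libraries, and the list did not pass with an estimated correlation (adjusted p = 0.82).

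The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The edgeR test called 0 genes in the real split and at most 0 in the others, and the same holds at least 2-fold. That 10 of 10 splits reached the real count decides nothing, since any split reaches a count of 0. DESeq2 called 179 in the real split and 229 in the highest other, and 2 of 10 splits reached the real count. That other split set shJUP 1, shJUP 3 and shNC 1 against the rest, which keeps both number-2 libraries together. The 4 splits that do so gave 229, 125, 43 and 24 genes with DESeq2, and the 5 others apart from the real one, which part them, gave 0 to 5. At an unadjusted p under 0.05 edgeR held 1594 genes in the real split and 2081 in the highest other. The 4 splits that keep both number-2 libraries together held 1334 to 2081, and the 5 others that part them 82 to 265. Camera passed 7 lists in the real split and 16 in the highest other, and 10 of 10 splits reached the real count. Among the 4 splits that part all 3 number pairs, DESeq2 called 179 in the real one and 1, 2 and 5 in the others, and 696 against 2, 12 and 17 with the block.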
